A study of Mus musculus with 9 samples.

How the data were processed

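Kidney RNA from wild-type and Bmal1 knockout C57BL/6 mice was profiled by 3′ mRNA sequencing in 4 and 5 libraries. Bmal1 (gene symbol Arntl) is the transcription factor that, paired with Clock or Npas2, drives the circadian clock through E-box sites. Per the labels' protocols, RNA was extracted with Trizol and 500 ng of total RNA entered each library, made with the Lexogen QuantSeq kit. This kit primes at the poly(A) tail and gives about a single tag near the 3′ end per transcript, so values do not need correction for gene length, and splice forms or deleted exons away from the 3′ end are not seen. The labels give neither the hour at which tissue was taken, nor sex, age, or which part of Bmal1 was deleted. They do not say that each library came from a separate animal, so p-values measure the spread between these libraries.

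The deposited values, 1 table per library, are on a log2 scale, log2(x + 1) with 3 decimals, for 23282 gene symbols. The submitters' processing notes name Bowtie2, bedtools and the mouse build mm10, without versions. Normalization tool, annotation, strand setting and treatment of reads shared between genes are not given in the sources used here. From the values, x is a read count that the authors adjusted towards a common library size: back-transformed values summed to 11765219 to 13486444 per library, and low values lay in narrow bands near whole numbers whose shift depended on both library and gene. Such values are not counts, so the count model planned before the data were examined was replaced by its planned substitute for normalized values. The raw depth is unknown. The band of single reads lay at x of 0.896 to 1.09, which puts the libraries within a narrow range of relative depth, 0.914 to 1.12.

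Of the 23282 symbols, 5113 were at 0 in all 9 libraries and 79 rows carried a symbol listed more than once. A gene was tested if x was at least 10 in at least 4 libraries, which kept 13481 symbols. This filter was chosen after the files were seen and before any test. The deposited values were fitted with limma 3.58.1 in R 4.3.3 (moderated test, prior variance following the mean expression), genotype as the single term, two-sided, with Benjamini-Hochberg adjustment over all 13481 genes and a threshold of 0.05. Fold changes are differences of log2(x + 1), which understate the change of genes near the floor. Library measures, and means of gene lists per library, were compared by exact permutation over all 126 splits of the 9 libraries into 4 and 5, where the smallest possible p is 0.00794.

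Before the data were examined, 52 gene lists were fixed for pathways, kidney cell types, other cell types that a kidney piece could hold, sex-biased genes and RNA quality. The 50 lists with at least 3 tested members were tested with camera, a competitive set test in limma, at a preset correlation of 0.01 between genes. Mitochondrially encoded genes had no tested member and are not analysed here, and the adrenal list had too few. Each call was set beside camera with a correlation estimated from these libraries. Genes named in the text followed a rule fixed in advance: Arntl and both clock lists; the 10 largest increases and 10 largest decreases among changed genes with a mean of at least 10 CPM in the higher genotype and no overlap between genotypes, predicted genes left out; up to 4 members with the smallest adjusted p of each list described; and the 2 most abundant members of cell-type and quality lists. Some genes that the rule names are not reported here. Genes named outside that rule are marked as chosen after their values were seen.

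Gene positions came from the GENCODE annotation of GRCm38, the assembly of mm10, in which 99.0% of tested symbols were found. Genes with near-identical copies, or with exons overlapping another gene, are uncertain, since the authors' handling of shared reads and strand is not stated. The globin symbols Hbb-b1 and Hbb-bs lay close together in all 9 libraries, at 14.35 and 14.376 in wild type 1 and 16.583 and 16.605 in knockout 4. The same reads thus appear to have been counted under both symbols. Overlapping genes may likewise share reads and count as separate changes, which was not tested. Among the named genes, exons of Acaa1b, Acsm3, Bst1, Ccnd1, Cfb, Cml5, Col4a1, Cp, Csf1r, Cyp24a1, Dbp, Ldhd, Nr1d1, Prlr, Pth1r, Timp3 and Usp2 overlap another protein-coding gene. Exons of Ace, Arntl, Bhlhe40, Bhlhe41, Bhmt, Cd55, Cdkn1a, Cdkn1c, Cry2, Cyp2a4, Elovl6, Fgg, Gclm, Hmgcs1, Krt7, Lox, Me1, Pdgfra, Rpl27a, Tef and Umod overlap a noncoding or unclassified transcript. Those of Ctgf, Jund and Nrp1 overlap a noncoding transcript too.

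The model was tested on simulated data with the real gene means and spread. Of the 67 genes changed by 1.5-fold in the simulation, 28.4% were recovered, against 67.2% of 67 at 2-fold and 97.0% of 66 at 4-fold. Far fewer genes were changed than the 1937 called in the real data. The adjusted threshold is stricter when fewer genes change, so these shares are not the recovery of the real comparison. Among the 13481 genes, 6 unchanged ones were called. The shifted list was called and 0 of 20 unchanged lists were. Simulated genes varied independently of each other, so this list result does not cover real lists, whose members can be correlated between libraries. Alternatives covered 4 scalings of the back-transformed values planned in advance, sample quality weights, filters on low values, pseudocounts, thresholds, each library left out in turn, the replicate number as a block, and other list tests. The setting without sex-chromosome and globin genes also scaled each library to the total of its remaining genes. Added after the data were seen were quantile normalization, scaling by the total without Rn45s, Rn45s as a covariate, robust variance estimation, removal of wild type 2 and knockout 4, and exact permutation of list means. Figures were drawn with matplotlib 3.10.9.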

Results

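Kidney transcriptomes of mice lacking the clock transcription factor Bmal1 were compared with those of wild-type mice, in a series on the circadian clock in chronic kidney disease. There were 4 wild-type and 5 knockout libraries, with adjusted totals of 11765219 to 13486444 and 13481 genes tested. Genotype separated the libraries along the first principal component, which held 35.9% of the variance. Wild type 2 stood apart from the other wild types on the second component. Pearson correlation across genes, which are not independent replicates, was 0.959 to 0.979 between wild types, 0.965 to 0.976 between knockouts and 0.943 to 0.964 between genotypes. No pair of files was identical.

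**Figure D1:**
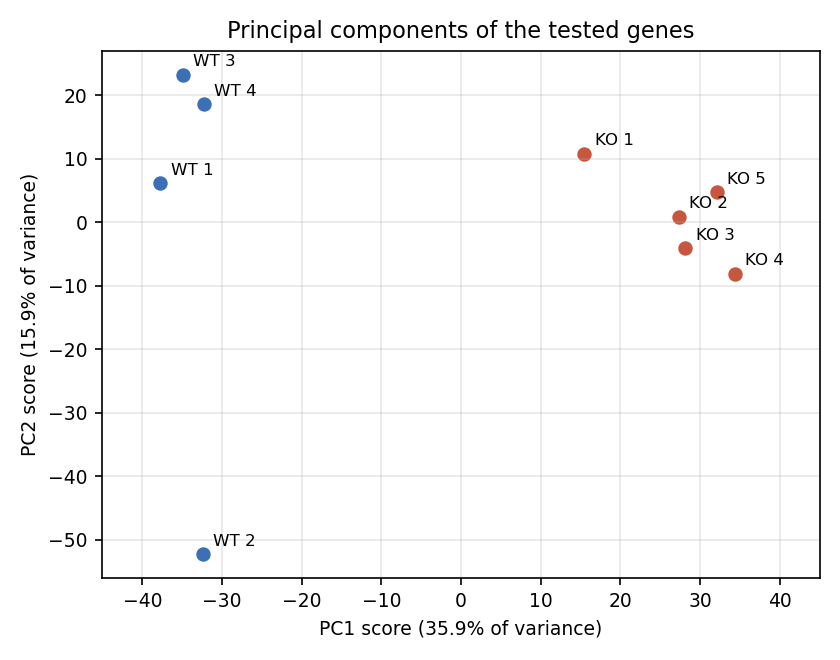
Scores of the 4 wild-type (WT, blue) and 5 knockout (KO, red) libraries on the first and second principal components of the tested genes. All wild types lie at negative and all knockouts at positive PC1 scores, and WT 2 lies at -52.2 on PC2.

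The libraries differed in makeup as well as genotype. Rn45s, the precursor of ribosomal RNA, took 7.43% ± 2.72 (SD, n = 4) of adjusted reads in wild type and 10.4% ± 2.92 (SD, n = 5) in knockout, with overlapping ranges (exact permutation p = 0.175, two-sided). Globin transcripts, a measure of blood, took 0.889% ± 0.437 and 1.72% ± 1.08 (exact permutation p = 0.159 over the same 4 and 5 libraries), with 1.54% in wild type 2 and 3.56% in knockout 4. These sums hold both Hbb-b1 and Hbb-bs, so reads counted under both symbols would enter more than once and raise the percentages. Kap, the androgen-regulated protein of proximal tubule cells and a highly abundant kidney transcript, took 4.44% ± 0.607 of reads in wild type and 2.89% ± 0.107 in knockout, lower in all 5 knockouts (exact permutation p = 0.00794, adjusted over 6 library measures 0.0238). More symbols lay above an x of 10 in knockout, 13400 ± 53.2 against 13150 ± 76.7 (exact permutation p = 0.00794).

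The first question was whether the targeted gene and the clock genes differed. Arntl (chromosome 7, 113207465 to 113314126, + strand, GRCm38) fell by 0.84 on the log2 scale (SE 0.21, limma adjusted p = 0.0113). Wild-type values were 6.68, 6.26, 7.06 and 6.76, and knockout values 5.95, 5.65, 5.99, 5.80 and 5.86, so that all 5 knockouts lay below all 4 wild types. The labels do not say which part of the gene was deleted; a 3′ tag outside it would still be read, so this decrease neither checks nor contradicts the genotype labels. Without wild type 3 the difference was -0.72 (adjusted p = 0.0552), and with Rn45s as a covariate -0.71 (adjusted p = 0.0526).

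Core clock genes changed in both directions. The labels do not give the hour of sampling, so the directions of clock genes given here may not hold at another hour. Among genes with E-box or D-box control, the Bmal1 targets Nr1d2 (log2 fold change -3.46, SE 0.18, limma adjusted p = 3.50e-10) and Nr1d1 (-1.72, SE 0.15, adjusted p = 2.25e-07), which encode the repressors REV-ERBβ and REV-ERBα, fell, as did the output transcription factors Dbp (-1.51, SE 0.25) and Tef (-0.60, SE 0.11). The repressors Per1 (1.16, SE 0.19), Per2 (1.605, SE 0.29) and Cry2 (1.54, SE 0.20) rose. Per3 had a log2 fold change of -1.36 (SE 0.49, adjusted p = 0.0726), and Hlf 0.11 (SE 0.09, adjusted p = 0.478); Bhlhe40, Bhlhe41, Usp2 and Wee1 did not pass either, and Ciart was below the filter. Of 13 tested members 3 rose and 4 fell, 3 and 5 adjusted over the list alone, and the list had no call by camera (adjusted p = 0.313). Its mean per library was lower in all 5 knockouts than in any wild type, by 0.339 (SE 0.11, exact permutation adjusted p = 0.0265), an alternative added after the data were seen. By fry the list was lower (adjusted p = 0.0169). Its median log2 fold change was -0.083, so members with large decreases carried the mean. Nr1d1 and Dbp have exons overlapping Thra and Sphk2 on the other strand and are uncertain in that respect.

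Most genes under ROR element control, the sites through which REV-ERB represses, rose. Cry1 had a log2 fold change of 3.13 (SE 0.19, limma adjusted p = 3.32e-09), Nfil3 2.58 (SE 0.35), the cell-cycle inhibitor Cdkn1a 2.38 (SE 0.14) and Npas2, the partner of Bmal1, 1.34 (SE 0.24). Gys2, liver glycogen synthase, fell by 1.45 (SE 0.32), and Clock was at 0.15 (SE 0.12, adjusted p = 0.439). Of 7 tested members 5 rose and 1 fell, also adjusted over the list alone, and Elovl3 was below the filter. The list was higher by camera (adjusted p = 4.82e-07) and with an estimated correlation (adjusted p = 0.0213). Among 12 other clock components, Rorb (-2.42, SE 0.62) and Ncoa2 (-0.61, SE 0.17) fell, and the list had no call (1 rose and 4 fell over the list alone; camera adjusted p = 0.408). Without wild type 3 neither passed (adjusted p = 0.0639 and 0.0698), nor with Rn45s as a covariate (0.0727 and 0.0752). Ncoa2 also failed without wild type 4 (0.0922) or knockout 4 (0.0507), with scaling to the library total (0.0526), also without Rn45s in it (0.0625), and without sex-chromosome and globin genes (0.0534).

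**Figure D2:**
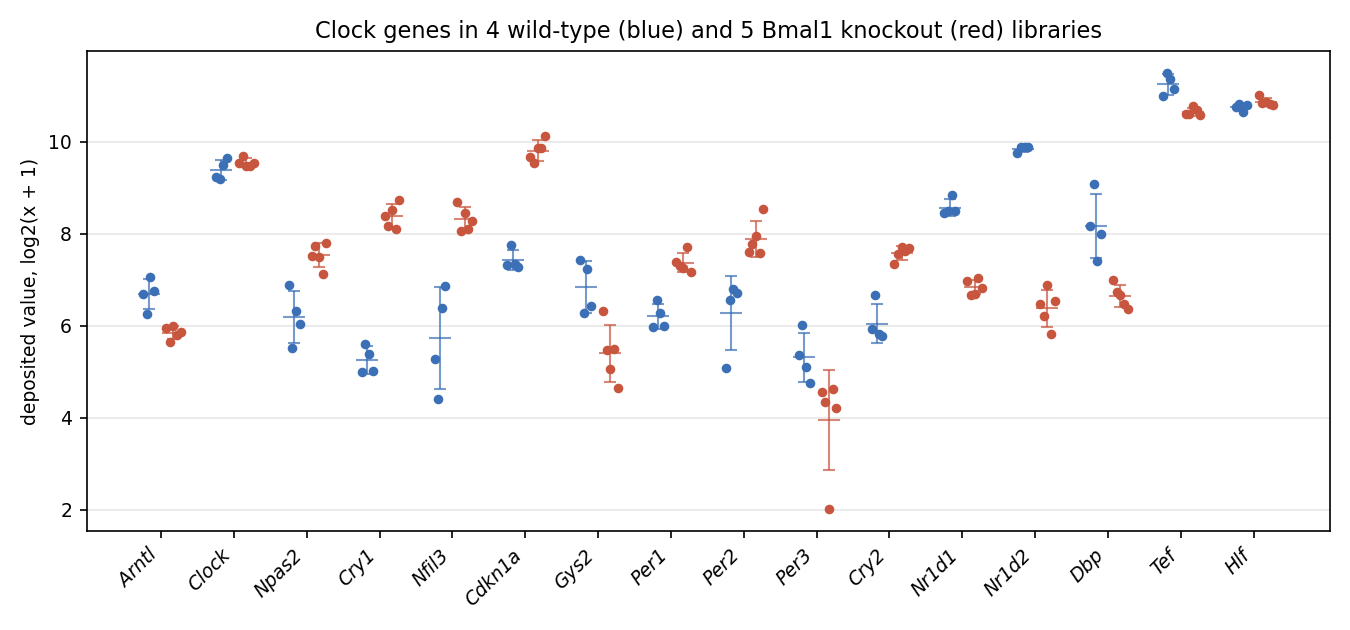
Deposited log2(x + 1) values of clock genes in 4 wild-type (blue) and 5 knockout (red) libraries; points are libraries, horizontal marks means and bars the SD. Cry1, Nfil3, Cdkn1a, Per1, Per2 and Cry2 lie higher in all knockouts than in any wild type, and Nr1d1, Nr1d2, Dbp and Tef lower.

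Over all genes, 1937 differed between genotypes, 831 higher and 1106 lower in knockout (limma, adjusted p under 0.05), and 1145 of them by at least 1.5-fold, 563 higher and 582 lower. At an unadjusted p under 0.05 there were 3708. All libraries of one genotype lay above all of the other in 1931 genes, 14.3% against 1.59% by chance, and 1496 of those were among the changed. The share of changed genes that were higher depended on scaling. It was 42.9% as deposited, 50.5% after quantile normalization, 58.1% with upper-quartile scaling and 56.8% with scaling to the library total. It was 58.8% with sex-chromosome and globin genes left out and scaling to the total of the rest, and 64.7% with scaling to the total without Rn45s. The last moved the median of all genes to 0.105 from 0.0002. Changes are given on the deposited scaling.

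The largest increases included several transporters and enzymes. Crabp1, a retinoic acid binding protein, rose by 5.89 on the log2 scale (SE 0.51, limma adjusted p = 2.17e-07) from values near the floor in wild type. The amino acid transporter Slc7a12 rose by 5.28 (SE 0.21), Bhmt, which remethylates homocysteine with betaine, by 4.58 (SE 0.24) and the prolactin receptor Prlr by 4.07 (SE 0.25). Loxl4, a lysyl oxidase, rose by 3.42 (SE 0.27), the water channel Aqp8 by 3.38 (SE 0.27), the fibrinogen chain Fgg by 3.13 (SE 0.21), the fatty acid hydroxylase Cyp4a14 by 3.07 (SE 0.40) and Kynu, of tryptophan breakdown, by 2.90 (SE 0.22), with Cry1 as given above. Prlr shares exon positions with the gene Gm21973 on the same strand, so its value is uncertain. Each was higher in all 5 knockouts than in any wild type, which the rule for naming these genes required.

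The largest decreases were led by cytochromes P450 and carboxylesterases. Cyp2a5 had a log2 fold change of -5.11 (SE 0.24, limma adjusted p = 9.71e-11), Ces1g -5.05 (SE 0.31), Cyp4a12a -4.98 (SE 0.36), Ces1d -4.19 (SE 0.15), Cyp2a4 -3.78 (SE 0.17) and Cyp4a12b -3.60 (SE 0.23). Cml5, now named Nat8f5, was at -4.50 (SE 0.38), Angptl7 at -4.403 (SE 0.59), Nkain1 at -3.52 (SE 0.37) and Nr1d2 as given above. Cyp2a4 with Cyp2a5, Cyp4a12a with Cyp4a12b, the Ces1 genes and Cml5 with Nat8f6 are near-identical or overlapping, so the split of reads within each family is uncertain. All were lower in each of the 5 knockouts than in any wild type, which the same naming rule required.

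Gene lists were called higher in 18 cases and lower in 7, out of 50 tested. With an estimated correlation 3 calls held: the ROR list and the kidney injury list higher, and the male-biased list lower. Exact permutation of the library mean of each list, added after the data were seen, passed 17 lists at adjusted p of 0.0265 or 0.0467, 15 of them among the 25 called. The others were the E-box or D-box clock list, lower, and amino acid metabolism and transport, higher. Their median log2 fold changes were -0.083 and -0.027, so these means were carried by members with large changes and not by the whole list. The calls outside those 15 are named where they occur.

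**Figure D3:**
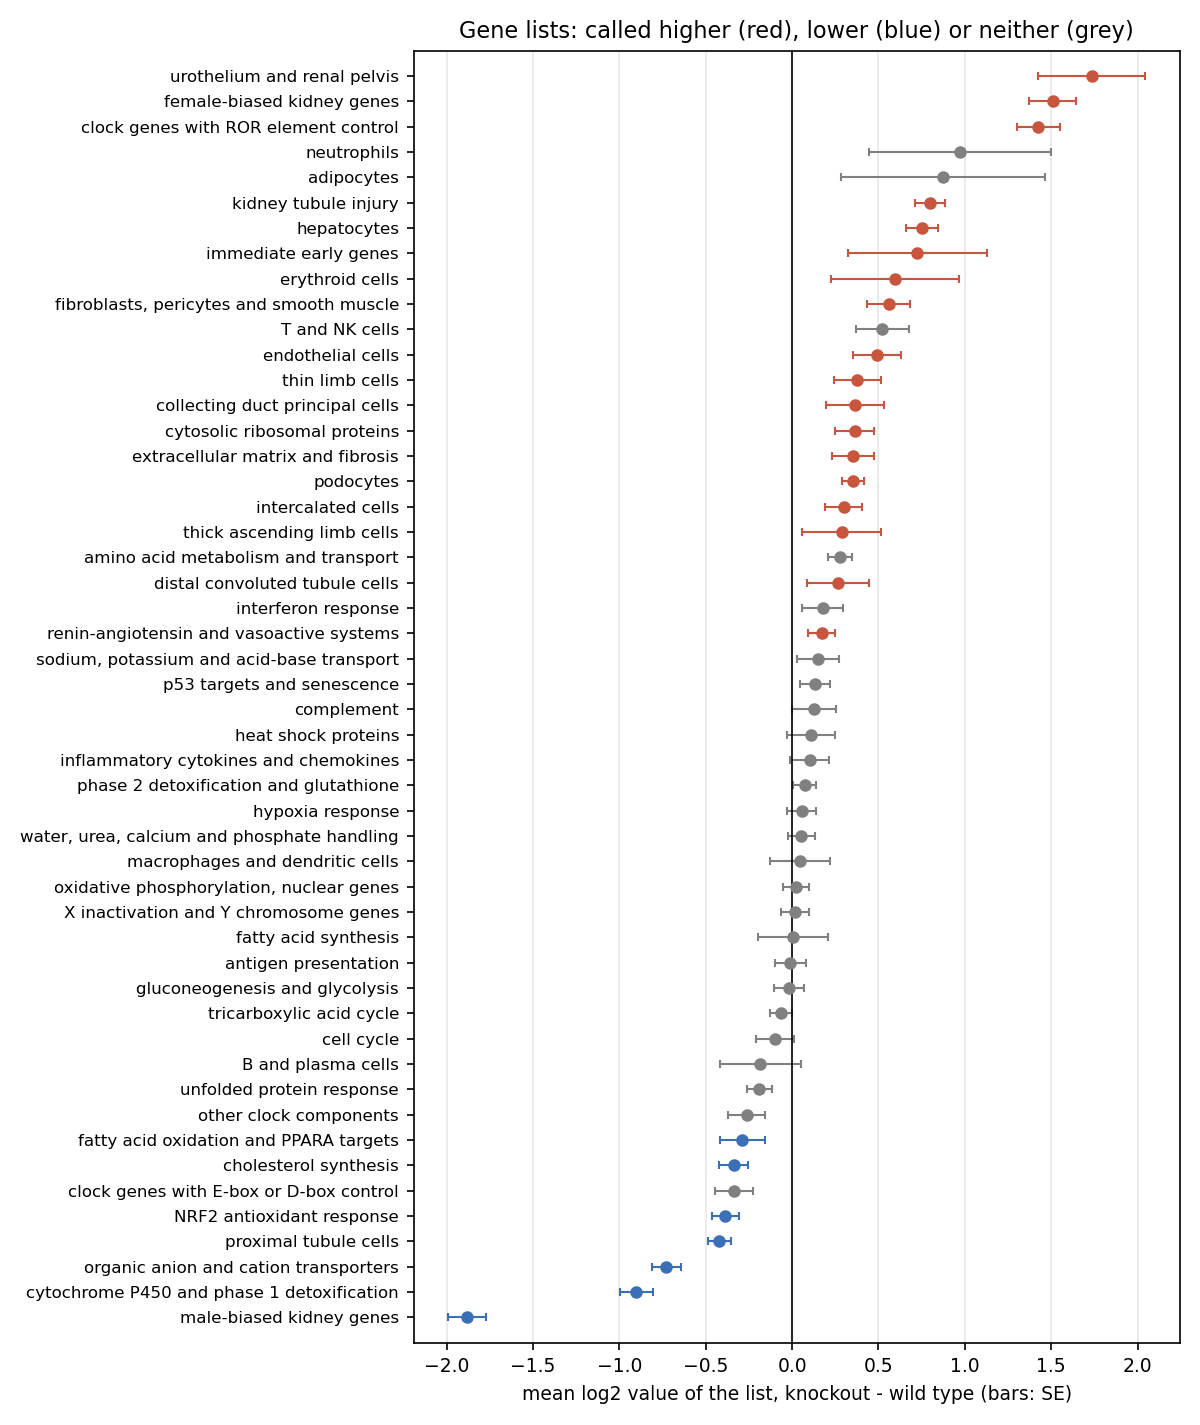
Difference in the mean log2 value of each of the 50 tested lists, knockout minus wild type, with SE bars over 4 and 5 libraries; colour gives the camera call at the preset correlation. Male-biased genes lie lowest at -1.88 and urothelial markers highest at 1.73.

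Sex-biased kidney genes shifted in both directions. Of 10 genes known to be higher in male kidney, 8 fell and none rose (9 fell and 1 rose adjusted over the list alone), with a median log2 fold change of -1.79; camera adjusted p was 1.61e-13, and 0.0213 with an estimated correlation. Examples were the organic anion transporter Slco1a1 (-3.04, SE 0.16), the acyl-CoA synthetase Acsm3 (-2.78, SE 0.18; its exons overlap Eri2), Cyp4b1 (-2.21, SE 0.15) and Cyp2j13 (-2.12, SE 0.15), the last 2 being cytochromes P450. Kap, the most abundant member, had -0.67 (SE 0.23, adjusted p = 0.0604). Of 7 tested genes on the list fixed in advance as female-biased, 5 rose, Slc7a12, Prlr, Hao2 (2.23, SE 0.12), Cyp4a14 and Slc22a29 (1.47). The other 2 fell, Cyp2a4, whose bias in kidney was not checked here, and Akr1c18 (-1.79). The list thus moved both ways around a median of 2.23. Its camera call (adjusted p = 0.000411) was lost with an estimated correlation (adjusted p = 0.0810). Slc22a29 and Akr1c18 were named after their values were seen. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d were expressed in all 9 libraries, with a mean difference of 0.0171 (SE 0.0807, exact permutation p = 0.857), and Xist was at most 3.22 on the log2 scale in any library.

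**Figure D4:**
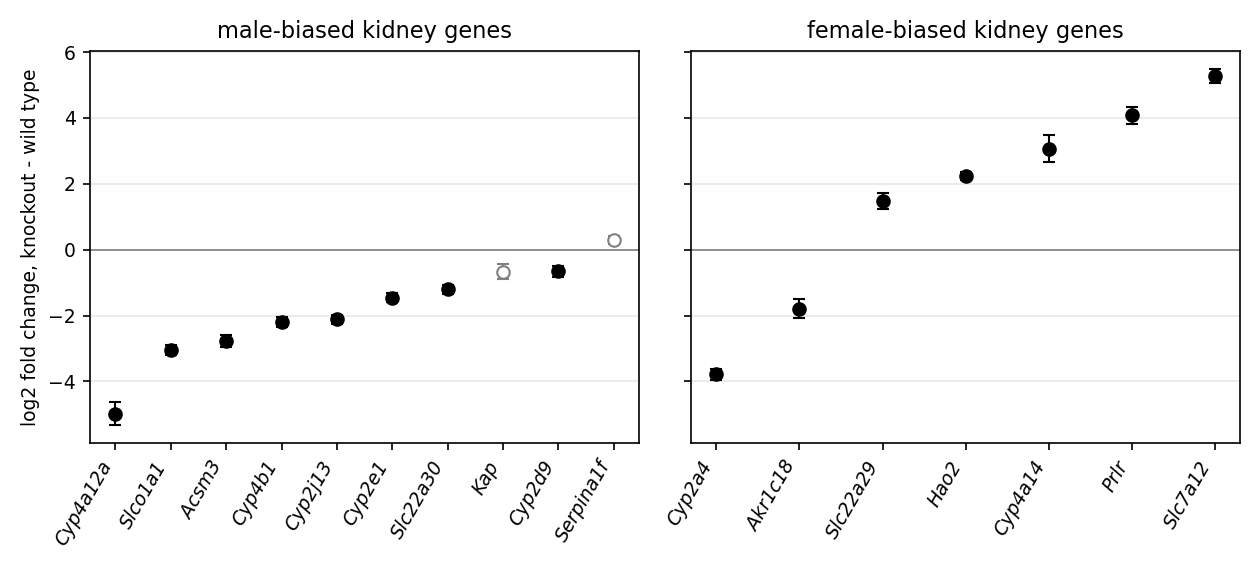
log2 fold change, knockout minus wild type, with SE for the tested male-biased (left) and female-biased (right) kidney genes; filled points passed adjusted p under 0.05. The 8 filled male-biased genes lie below 0, and Cyp2a4 and Akr1c18 lie below 0 among the female-biased.

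Lists of organic anion and cation transporters, phase 1 detoxification genes and proximal tubule markers were called lower. These lists share members with the male-biased list and with each other, so their calls are not independent. Among others, the male-biased list shares Cyp4b1, Cyp2j13 and Cyp4a12a with phase 1 genes, Slco1a1 with transporters and Kap with proximal tubule markers. Slc22a6 and Slc22a8 are in both the transporter and proximal tubule lists. Phase 2 detoxification genes had no call, as given below. Of 29 organic anion and cation transporters 18 fell and 2 rose (20 and 2 over the list alone), median -0.74, led by Slco1a1, Slco3a1 (-1.34, SE 0.12), Slc22a8, which encodes the basolateral anion exchanger OAT3 (-1.32, SE 0.13), and Slc22a6, encoding OAT1 (-1.21, SE 0.12). Camera adjusted p was 1.48e-12 and 0.0810 with an estimated correlation. Of 36 cytochrome P450 and phase 1 genes 18 fell and 6 rose (19 and 8 over the list alone), median -0.71, led by Ces1d, Cyp2a4, Cyp2a5 and Cyp4a12b (camera adjusted p = 1.72e-09, 0.0810 with an estimated correlation). Of 27 proximal tubule markers 9 fell and none rose (13 fell over the list alone), median -0.34, with Ggt1 (-0.89, SE 0.10), γ-glutamyltransferase, and the dicarboxylate transporter Slc13a3 (-0.96, SE 0.13) beside Slc22a6 and Slc22a8 (camera adjusted p = 1.17e-06, 0.175 with an estimated correlation).

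Fatty acid oxidation, cholesterol synthesis and antioxidant lists were lower with smaller changes, with medians near the -0.34 of proximal tubule markers. Whether a lower share of proximal tubule cells gave these decreases was not tested. Of 37 genes of fatty acid oxidation and PPARA targets 17 fell and 1 rose (20 and 1 over the list alone), median -0.35, with Acadl (-0.88, SE 0.10) and Acaa1b (-0.89, SE 0.14) lower and Cyp4a14, the ω-hydroxylase, higher. Camera adjusted p was 2.75e-06, 0.344 with an estimated correlation and 0.0627 by permutation. Exons of Acaa1b overlap a gene on the other strand. Of 23 cholesterol synthesis genes 5 fell (13 over the list alone, where 1 rose), median -0.39, with Mvd (-0.64, SE 0.11), Sqle (-0.90, SE 0.17) and Hmgcs1 (-0.58, SE 0.12); camera adjusted p was 0.000219, and 0.211 with an estimated correlation. Of 14 NRF2 antioxidant genes 7 fell (9 over the list alone), median -0.39, among them Gclm (-0.62, SE 0.10), Osgin1 (-0.74, SE 0.16) and heme oxygenase Hmox1 (-1.17, SE 0.28); camera adjusted p was 0.000219, and 0.175 with an estimated correlation. Nuclear oxidative phosphorylation genes had a median of 0.03 (1 of 51 fell, 1 over the list alone; camera adjusted p = 0.538), and were called higher after quantile normalization (0.000181).

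Genes of tubule injury were higher. Of 21 tested 12 rose and 2 fell (14 and 3 over the list alone), median 0.59, with the fibrinogen chains Fgg, Fgb (2.14, SE 0.18) and Fga (2.89, SE 0.32) and ceruloplasmin Cp (1.96, SE 0.16) leading. Camera adjusted p was 2.35e-07, and 0.0352 with an estimated correlation. The members that fell were Hmox1 and the lipid droplet gene Plin2 (-0.38), the latter chosen after its value was seen. Spp1, the most abundant and likewise chosen afterwards, had 0.46 (adjusted p = 0.0549). The 3 fibrinogen chains were also the members with the smallest p of the hepatocyte list, in which 5 rose and 1 fell of 13 (the same counts over the list alone), median 0.42, camera adjusted p 0.00549 and 0.0810 with an estimated correlation. At a mean of at least 5 CPM the hepatocyte median was 0.12 (camera adjusted p = 0.0402). Albumin Alb fell by 2.02 (SE 0.25).

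Cytosolic ribosomal protein genes rose together by a small amount: 37 of 69 rose and none fell (52 rose over the list alone), median 0.37, with Rps16 (0.59, SE 0.12), Rpl37 (0.60, SE 0.13), Rpl27a (0.54, SE 0.12) and Rps3a1 (0.52, SE 0.12) leading. Camera adjusted p was 3.76e-18, but members were correlated at 0.662 between libraries and the call was lost with an estimated correlation (adjusted p = 0.344). The share of Rn45s ranged from 5.07% to 14.4% over the same libraries and averaged higher in knockout, as given above.

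Lists for several cell types other than the proximal tubule were also called higher, but that of macrophages and dendritic cells was not. Of 9 urothelial markers 6 rose (9 over the list alone), median 1.90, with keratin 15 Krt15 (3.22, SE 0.54), Psca (2.74, SE 0.53), uroplakin Upk1a (2.06, SE 0.34) and Krt7 (0.80, SE 0.13); camera adjusted p was 3.19e-07, and 0.101 with an estimated correlation. At a mean of at least 5 CPM the urothelial median was 0.80 and the list was still called (0.00250). Of 20 endothelial markers 8 rose (9 over the list alone), median 0.45, with Plvap (1.03, SE 0.16) and Pecam1 (0.83, SE 0.15) leading. Nrp1, an abundant member, had a call in none of 25 alternatives. For the endothelial list camera adjusted p was 6.86e-06, and 0.328 with an estimated correlation. Of 18 fibroblast, pericyte and smooth muscle markers 4 rose (11 over the list alone), median 0.50, led by Dcn (0.66, SE 0.14) and Pdgfra (0.84, SE 0.21); camera adjusted p was 3.65e-05, and 0.0810 with an estimated correlation. Pdgfra did not pass without wild type 2 and knockout 4 (0.0587) or with Rn45s as a covariate (0.0681). Of 16 podocyte markers 2 rose, Cdkn1c (0.56, SE 0.11) and Wt1 (0.57, SE 0.19), and 5 over the list alone, median 0.33; camera adjusted p was 0.000558, and 0.0810 with an estimated correlation. Wt1 did not pass on leaving out wild type 1, 3 or 4 or knockout 2, 3, 4 or 5 (adjusted p 0.0663 to 0.130), without a filter (0.0788), with a pseudocount of 5 (0.0501), with quantile normalization (0.0959) or with Rn45s as a covariate (0.193). The 22 macrophage and dendritic markers had a median of 0.02, with 1 that fell, Csf1r (-0.48, SE 0.10), also over the list alone (camera adjusted p = 0.929).

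Some distal nephron markers rose, and none of these calls passed exact permutation of the list mean. In intercalated cells 5 of 17 rose (8 rose and 1 fell over the list alone), median 0.36, with Rhcg (0.63, SE 0.12) and Slc4a1 (0.96, SE 0.20); camera adjusted p was 0.00269, and 0.411 with an estimated correlation. In the thick ascending limb 5 of 13 rose (6 rose and 1 fell over the list alone), with Ppp1r1a (0.54, SE 0.10) and Sostdc1 (0.54, SE 0.13), while Umod, the most abundant, had -0.47 (adjusted p = 0.0670); camera adjusted p was 0.00725, and 0.459 with an estimated correlation. In the distal convoluted tubule 5 of 11 rose (6 over the list alone), with Cldn8 (0.71, SE 0.14) and Calb1 (0.58, SE 0.15); camera adjusted p was 0.0284, and 0.459 with an estimated correlation. In principal cells 5 of 14 rose and 1 fell (7 and 1 over the list alone), with Npnt (0.71, SE 0.13) and Fxyd4 (0.77, SE 0.14); camera adjusted p was 0.0220, and 0.411 with an estimated correlation. In the thin limb 2 of 10 rose, also over the list alone, Cldn4 (0.94, SE 0.26) and Bst1 (0.79, SE 0.25); camera adjusted p was 0.0412, and 0.328 with an estimated correlation. Without wild type 2 the calls of the last 4 lists ended, at adjusted p of 0.0890, 0.166, 0.103 and 0.0930. Without wild type 1 those of the thick limb (0.0574), convoluted tubule (0.104) and thin limb (0.0692) ended, without knockout 1 those of the convoluted tubule (0.0872), principal cells (0.0526) and thin limb (0.0660), and without knockout 5 that of the thin limb (0.149). With sample quality weights the calls of the same 4 lists ended at 0.109, 0.146, 0.0862 and 0.0995, without wild type 2 and knockout 4 at 0.0734, 0.126, 0.0631 and 0.0623, and by fry at 0.156, 0.177, 0.132 and 0.0699. That of the thin limb ended further with upper-quartile scaling (0.0504), scaling to the library total (0.0549) or to the total without Rn45s (0.0602), and without sex-chromosome and globin genes (0.0575). Cldn4 did not pass without wild type 1 or 3 or knockout 3 or 5 (0.0506 to 0.0589), nor Bst1 without wild type 1, 3 or 4 or knockout 1, 2 or 5 (0.0778 to 0.133), without a filter (0.0827), with quantile normalization (0.0925) or with Rn45s as a covariate (0.122).

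Vasoactive and hormone-handling genes changed in both directions. Of 27 renin-angiotensin and vasoactive genes 6 rose and 2 fell (8 and 3 over the list alone), median 0.29. Hsd11b1, which regenerates corticosterone, fell by 1.73 (SE 0.15, limma adjusted p = 2.18e-07) and the angiotensin-converting enzyme Ace by 1.09 (SE 0.14), while the neutral endopeptidase Mme rose by 1.10 (SE 0.12). The list call (camera adjusted p = 0.0433) was lost with an estimated correlation (adjusted p = 0.344), by permutation (0.168), and on leaving out wild type 1 (0.0789), wild type 2 (0.126), knockout 1 (0.0660), knockout 2 (0.0552) or knockout 4 (0.0782). It was also lost with scaling to the library total (0.0721) or by upper quartile (0.0678), to the total without Rn45s (0.0933) or without sex-chromosome and globin genes (0.0776). Quality weights (0.122), no filter (0.0643) and removal of wild type 2 and knockout 4 (0.196) ended it too.

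Matrix, immediate early and erythroid lists were called higher but did not pass exact permutation of the list mean. Of 37 extracellular matrix genes 9 rose and 1 fell (13 and 1 over the list alone), median 0.44, with the lysyl oxidase Lox (2.80, SE 0.22), Col4a1 (0.67, SE 0.14) and Dcn higher and the inhibitor Timp3, the most abundant, lower (-1.11, SE 0.12); camera adjusted p was 0.000419, and 0.411 with an estimated correlation. Of 23 immediate early genes 3 rose, also over the list alone, Klf2 (1.00, SE 0.22), Klf4 (0.68, SE 0.16) and Myc (2.21, SE 0.66), median 0.53. The most abundant members, Ctgf and Jund, had a call in none of 25 alternatives. For this list camera adjusted p was 0.000484, and 0.411 with an estimated correlation. Of 12 erythroid genes 1 rose, also over the list alone, the anion exchanger Slc4a1, which intercalated cells also express. For the erythroid list camera adjusted p was 0.00307, and 0.459 with an estimated correlation. Its members Hbb-b1 and Hbb-bs appear to hold the same reads but were counted separately. Myc did not pass on leaving out wild type 2 or 3 or knockout 2, 3, 4 or 5 (adjusted p 0.0525 to 0.0845), with quality weights (0.0777), a pseudocount of 0.1 (0.0535) or quantile normalization (0.0527), or without wild type 2 and knockout 4 (0.130). With Rn45s as a covariate the immediate early (median 0.13, adjusted p = 0.212) and erythroid (0.130) calls ended, and without sex-chromosome and globin genes the erythroid call ended (0.126). By fry the matrix (0.0725), immediate early (0.156) and erythroid (0.216) lists had no call.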

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

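The tests on sex-biased genes and on urothelial markers were chosen after those results were seen; the counts over other splits, and the tests on ribosomal protein genes, were written down before their values were computed, although the rise of the ribosomal genes had been seen.

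Single libraries lay far from the rest of their genotype in 11 of 138 groups of values, where chance gives about 6.9. Of reads in knockout 2, 3.08% were Kap (others 2.83% to 2.89%), and of those in wild type 2, 1.54% were globin (0.619% to 0.731%). In wild type 1 Per2 was at 5.09 on the log2 scale (others 6.55 to 6.79) and Nr1d2 at 9.75 (9.87 to 9.89). In wild type 2 Cry2 was at 6.67 (5.77 to 5.92), Cdkn1a at 7.75 (7.28 to 7.34) and the cholesterol synthesis mean at 8.41 (8.69 to 8.74). Nr1d1 was at 8.84 in wild type 3 (8.45 to 8.48). Per3 was at 2.01 in knockout 3 (4.21 to 4.61), Clock at 9.70 in knockout 2 (9.47 to 9.53) and the urothelial mean at 7.21 in knockout 5 (5.90 to 6.28).

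Chance was an unlikely source of the gene counts, though the smallest share this test could give was 1 in 100. Of 100 splits of the 9 libraries into 4 and 5 drawn at random, 1, the real split, gave as many as 1937 changed genes, and the highest other gave 940. Likewise 1, the real split, gave as many as 1145 genes at 1.5-fold, and the highest other gave 660. The split with 940 set knockouts 2 to 5 against the wild types with knockout 1, a near copy of the real split. For the number of called lists chance cannot be excluded: 6 of 100 splits gave at least the 25 of the real split, the highest other giving 26.

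Male-biased genes were lower and most female-biased genes higher in knockout. Female knockout animals would lower the Y-linked genes, and these differed by 0.0171 (SE 0.0807), which argues against it. A lower share of proximal tubule cells alone would lower other proximal tubule markers by as much, but male-biased genes fell below 26 of these markers by a further amount, a difference of -1.47 (SE 0.102). A reduced male-type, androgen-dependent program in the knockout is a hypothesis that these results leave open, and no hormone was measured. Of the list fixed in advance as female-biased, Cyp2a4 and Akr1c18 fell. Whether Cyp2a4 is female-biased in kidney was not checked here, so its fall counts neither for nor against the hypothesis.

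Ribosomal protein genes were higher together. Lists matched on expression and on the longest annotated transcript had a median of -0.0139 (the highest of 10000 such lists 0.129) against 0.367. A trend with expression and that annotated length thus does not account for it. The longest annotated transcript need not be the expressed one (Rps20 3706 bp, ribosomal median 1109 bp), so a trend with expressed length was not tested. Genes of the matched lists were drawn singly, so their spread lacks the correlation among ribosomal genes. The lowest median over 6 other scalings was 0.382. Most of these use a single factor per library, which moves all genes alike and could not change how far the ribosomal genes lay from the rest. Quantile normalization, which is not such a factor, gave 0.4825. An adjustment that differs by gene was not tested as a source. With Rn45s as a covariate the mean shift was 0.283 (SE 0.108) against 0.362 (SE 0.114) without, and with 9 libraries the share of Rn45s cannot be told apart from genotype as a source. A response of ribosome production to Bmal1 loss remains untested.

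Urothelial markers were higher in knockout. Fewer proximal tubule cells alone would raise all other cell types alike, but the urothelial mean rose beyond the macrophage mean by 1.69 (SE 0.356). Macrophage markers rose little (0.045). Endothelial (0.490), fibroblast (0.559) and podocyte (0.351) means rose more, so the excess of the urothelial mean (1.73) over those was smaller, and it was not tested. More renal pelvis in the knockout pieces would raise the uroplakins equally, and the largest and smallest difference, of Upk1a and of Upk2 (1.32, SE 0.494, adjusted p = 0.0865, not passed), lay 0.744 (SE 0.423) apart, less than 2 SE. Fat markers followed only in part: Cfd was at 6.14, 5.10, 4.70 and 9.81 in knockouts 2 to 5 against at most 3.42 in wild type, but at 0 in knockout 1, whose urothelial mean was 6.03. Uneven dissection may account for this pattern and stays open; a larger urothelium in the knockout would look the same and was not tested.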

How the results depend on the processing

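Quantile normalization, scaling without Rn45s, Rn45s as a covariate, robust variance, removal of wild type 2 and knockout 4, and exact permutation of list means were chosen after the data were seen. No named gene or list with a call reversed, but the balance of calls did. There were more higher than lower genes with upper-quartile scaling (1123 and 811), the library total (992 and 756) and quantile normalization (890 and 873). The same held with scaling to the total without sex-chromosome and globin genes (1059 and 742) and to the total without Rn45s. Leaving out each library in turn gave 1426 to 2277 changed genes (610 to 1011 higher, 816 to 1266 lower), 972 to 1348 at 1.5-fold, 21 to 27 called lists, 13 clock genes past the threshold, and Arntl at -0.98 to -0.72; Arntl missed the threshold without wild type 3 (adjusted p = 0.0552). At an adjusted p of 0.01 there were 992 genes (387 higher, 605 lower), 327 of the higher ones at 1.5-fold, by construction of the stricter threshold. Scaling to the total without Rn45s gave 1272 higher and 695 lower, as that scaling moved the median of all genes. Rn45s as a covariate gave Arntl at -0.71 (adjusted p = 0.0526) and 1356 genes; the cause was not tested. An estimated correlation left 2 lists higher, 1 lower and 3 in all, permutation of list means passed 10 higher and 7 lower, and for neither was the cause tested. Without wild type 2 and knockout 4, 1874 genes changed, 1565 of them shared with the 1937. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.151, 0.0009, -0.0070 and 0.0407 by title, where wild types 1 and 4 but not 2 and 3 correlated best with their own number, and at 0.151, 0.0885, -0.0556 and -0.0002 by the second label. With the replicate number as a block, 1739 (title) and 1584 (second label) genes changed. The title block ended the call of the thin limb list (0.140) and of 11 named genes, among them Wt1 (0.0533), Bst1 (0.0782), Cldn4 (0.0762) and Myc (0.0564). The second-label block ended no list call but those of 15 named genes, among them Wt1 (0.112), Bst1 (0.132) and Ncoa2 (0.0524). Among named genes 5238 comparisons with an alternative kept their side of the threshold, 271 lost and 161 gained a call; among lists 1248, 68 and 30. The planned count-based test was not run because the values are not counts. Raw depth is unknown, though the band of single reads at x of 0.896 to 1.09 puts x near the number of reads assigned to a gene. How far read numbers limit low genes was not computed.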

Other observations

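Several lists without a camera call held large changes both ways. In amino acid metabolism and transport 6 of 36 rose and 7 fell (6 and 9 adjusted over the list alone, camera adjusted p = 0.919), median -0.027. The mean of the list was higher in all 5 knockouts, by 0.279 (SE 0.0705, exact permutation adjusted p = 0.0265), carried by a few large increases. Beside Slc7a12, Bhmt and Kynu, Hpd of tyrosine breakdown rose by 1.68 (SE 0.19, limma adjusted p = 7.47e-06). Slc7a13, the most abundant and chosen after its value was seen, fell by 1.22. In phase 2 detoxification 5 of 30 rose and 8 fell (9 and 9 over the list alone; camera adjusted p = 0.726), with Gsta1 (1.94, SE 0.17) and Gsta2 (1.74, SE 0.10), near-identical and so uncertain, higher, and Gsta3 (-1.18, SE 0.13) and Nat8 (-1.14, SE 0.11) lower. In water, urea, calcium and phosphate handling 4 of 26 rose and 4 fell (6 and 7 over the list alone; camera adjusted p = 0.921): the urea transporter Slc14a1 (2.31, SE 0.27) and the calcium-binding S100g (1.34, SE 0.17) were higher, and the vitamin D hydroxylase Cyp24a1 (-2.19, SE 0.29) and parathyroid hormone receptor Pth1r (-0.58, SE 0.10) lower.

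Glucocorticoid- and aldosterone-responsive Tsc22d3 (1.54, SE 0.12) and Sgk1 (1.59, SE 0.13) led the sodium, potassium and acid-base list, in which 9 of 39 rose and 5 fell (12 and 7 over the list alone; camera adjusted p = 0.0935, called on leaving out wild type 3, 0.00782, wild type 4, 0.0341, knockout 2, 0.0476, or knockout 4, 0.0319). Among 18 complement genes 2 rose and 2 fell, the same adjusted over the list alone: Cfi (1.99, SE 0.38) and Cd59a (0.50, SE 0.11) were higher and Cfb (-1.31, SE 0.12) and Cd55 (-2.32, SE 0.38) lower (camera adjusted p = 0.858). The epithelial chemokine Ccl28 fell by 2.52 (SE 0.23) in a cytokine list with no call (camera adjusted p = 0.832), and the interferon list stood at camera adjusted p 0.05003, with 3 of 29 higher (1 over the list alone). Leaving out wild type 4 (0.00555), knockout 1 (0.0207) or knockout 3 (0.0319) gave it a call.

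The remaining 13 lists had no call either, though single members changed. Malic enzyme Me1 (-0.95, SE 0.10) and the desaturase Fads1 (-0.70, SE 0.12) fell and the elongase Elovl6 (1.02, SE 0.20) rose in fatty acid synthesis (camera adjusted p = 0.424). Ldhd, a D-lactate dehydrogenase whose exons overlap Znrf1 on the other strand, fell by 1.75 (SE 0.11) in the glycolysis list (0.692), Edem1 fell by 1.05 (SE 0.13) in the unfolded protein response (0.0743) and cyclin Ccnd1, which overlaps another gene in the same way, fell by 0.82 (SE 0.12) in the cell cycle list (0.816). Among adipocyte genes (0.721) lipoprotein lipase Lpl fell by 1.46 (SE 0.13), while Cidec (3.36, SE 1.19, limma adjusted p = 0.0674), Cfd (3.42, SE 1.26, 0.0810) and Fabp4 (0.74, SE 0.34, 0.163) did not pass. Knockout 5 held Cidec at 8.77 and Cfd at 9.81, and knockout 1 held both at 0; the list mean differed by 0.873 (SE 0.592, exact permutation adjusted p = 0.313). The plasma cell gene Jchain fell by 1.96 (SE 0.39) among B and plasma cell genes (0.690), and did not pass with robust variance (adjusted p = 0.0657). The other camera adjusted p were 0.550 for the tricarboxylic acid cycle, 0.995 for heat shock proteins, 0.995 for p53 targets, 0.550 for antigen presentation, 0.979 for hypoxia, 0.124 for neutrophils and 0.256 for T and NK cells. Leaving out wild type 2 or knockout 5 gave a call to neutrophils (0.0285 and 0.0414) and to the unfolded protein response (0.0367 and 0.0214). Other alternatives gave calls as well. By fry T and NK cells were higher (adjusted p = 0.0394) and the unfolded protein response lower (0.0398). Without a filter on low values camera called T and NK cells (0.0377), adipocytes (0.0208), neutrophils (0.025) and the unfolded protein response (0.0154).

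Among the wild types, wild type 2 held the highest Dbp (9.08, others 7.41 to 8.16) and Per3 (6.02, others 4.76 to 5.36) and the lowest Arntl (6.26, others 6.68 to 7.06), Npas2 (5.50, others 6.04 to 6.88) and Nfil3 (4.41, others 5.27 to 6.87) on the log2 scale. The same library had the most Rn45s of the wild types, 11.3%. This library and these genes were singled out after their values were seen.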
